A study of Mus musculus with 8 samples.

How the data were processed

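The series holds 8 arrays of total RNA from mouse 3T3 cells, 2 for each of 4 transductions (vector, Dppa4, cMyc and SV40). Per the labels, RNA was checked on a Bioanalyser, copied into biotin-labelled cRNA and measured on Illumina bead arrays. Values were then exported with GenomeStudio, whose version the labels do not give. The deposited non-normalized table gives, per the file headers, an intensity for each of 25697 probes on each array, the mean brightness of its beads with neither background subtraction nor normalization, for which the median of an array lay between 84.9 and 95.2. The detection p-value of each probe, as deposited, is a p_value that GenomeStudio computed against the negative control beads of the array. A further deposited table holds an intensity that the authors had quantile-normalized between arrays on the linear scale. Its ranks followed those of the raw signal (lowest rank correlation 0.99999). Each column was matched to its sample by its name.

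The raw signal was background-corrected and quantile-normalized on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the detection p as the source of the negative control distribution. Probes with a detection p under 0.05 on both arrays of at least 1 group were kept (11054 probes). Probes were named by the current symbol of their Entrez gene (16938 probes), RefSeq accession (7420) or symbol (465), and 874 kept the name in the file. Of several kept probes for a gene, the one with the highest mean was used (2085 genes had more than 1), which left 8208 genes. A gene above background on neither array of a group has only a lower bound for its fold, printed as "at least"; the lowest normalized value of a detected probe stands in for the background. A gene above background on 1 of the 2 arrays keeps its fitted value, which rests there on a signal near the background.

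Groups were compared with limma (lmFit and eBayes, no trend) in 1 model of all 4 groups, with 4 residual and 6.14 prior degrees of freedom, in 6 contrasts. P-values were adjusted by the Benjamini-Hochberg method over all genes within a contrast, at a threshold of 0.05. Log2 fold changes are given with the standard error of the model, raw signals with the SD of 2 arrays, and in a run of genes the second number in parentheses is the adjusted p. Before the data were examined, 39 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 5 measured genes were tested with camera at its preset correlation of 0.01, adjusted over the lists within a contrast, with camera at an estimated correlation and with fry. Counts in a list are genes past the threshold over all genes tested, and a further count is adjusted over the list alone. Lists with fewer measured genes were counted but not tested.

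Genes were named by rule: Dppa4 and Myc; per contrast against vector, the 8 largest increases and 8 largest decreases past the threshold in which both arrays of 1 group lay above both of the other; up to 3 genes of each list called and up to 2 of any other list described; per contrast between oncogenes, 5 and 5 by the same criterion; and 6 and 6 of the genes changed alike against vector in all 3. Predicted or clone-like symbols were skipped. The result of 1 gene that the rule chose is not reported. Overlaps of contrasts that share the vector arrays were set beside those of independent contrasts. Correlations and covariances of their fold changes were set beside 100 simulations of groups without changes that share a control, with the same spread per gene in each group. Enrichment of the lists among shared genes used Fisher's exact test on the 8208 genes.

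Alternatives were no background correction, an offset of 50, median scaling, cyclic loess, the authors' normalized values, no probe filter, a detection p under 0.01 on all 8 arrays, the mean of the kept probes or all probes separately, eBayes with trend and robust, a fit of the compared groups alone, array weights, a replicate block, a 2-fold minimum, and leaving out each array. Chromosomes were assigned to genes from the mouse RefSeq annotation. The pipeline was tested on simulated data with the gene means and spreads of these arrays: for Dppa4 against vector, with 8208 genes, it recovered 36 of 100 genes changed by 1 on the log2 scale (median estimate 1.01) and 85 of 100 changed by 2 (median 2.02), with 2 calls among unchanged genes. In this simulation, with 2 arrays per group, a change of 1 on the log2 scale was thus missed at most of the changed genes. The spreads were shuffled among genes and few genes were changed, so these shares need not hold in the real contrasts. The groups are too small for permuting labels or for a test of outlying arrays. No SV40 transcript was measured, since the array holds mouse probes.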

Results

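Gene expression was measured in 3T3 cells, an immortalized line of mouse embryonic fibroblasts, on Illumina bead arrays, where biotin-labelled copies of cellular RNA bind to probes on beads. The 8 arrays fell into 4 groups of 2. The control group had received the vector. The other groups came from foci, patches of cells that pile up after transformation, grown on after transduction with Dppa4, cMyc or SV40. Dppa4 encodes a nuclear protein of pluripotent cells, cMyc a transcription factor of growth and division, and SV40 is a DNA tumour virus whose large T antigen binds p53 and the Rb proteins. The sample notes do not say which SV40 sequence was used, nor whether the arrays of a group stand for separate foci, cultures or RNA samples, so each error below covers the spread between these arrays alone. The median raw signal of an array lay between 84.9 and 95.2 units, and between 10158 and 11009 of the 25697 probes (39.5% to 42.8%) were above background. The number of arrays limits the precision.

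Across the 8208 genes tested, the arrays of 1 group correlated at r = 0.992 for vector, 0.984 for Dppa4, 0.970 for cMyc and 0.968 for SV40 (across genes, which are not independent replicates). Between groups, the mean r was highest for Dppa4 with SV40, at 0.957, and lowest for vector with Dppa4, at 0.909. The first principal component held 46.7% of the variance and placed the vector arrays at -39.8 and -39.4, the cMyc arrays at -8.38 and -23.5, the SV40 arrays at 26.6 and 16.5 and the Dppa4 arrays at 33.1 and 34.9. The arrays of a group differed more than 2-fold at 8 genes in vector, 90 in Dppa4, 400 in cMyc and 452 in SV40.

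Dppa4 and Myc were first read from their own probes. The Dppa4 probe that starts at base 372 of the transcript gave a raw signal of 578 ± 314 units (SD, n = 2) in the Dppa4 group and 89.5 ± 0.495 in vector, 88.8 ± 1.63 in cMyc and 82.9 ± 6.29 in SV40, where it was not above background. After normalization Dppa4 was at least 18.1-fold higher in the Dppa4 group than in vector (log2 fold change 4.44 ± 0.33 SE, adjusted p = 3.2e-05). That probe spans 2 stretches of chromosome 16, from 48289298 to 48289318 and from 48289441 to 48289469, on a genome build that the array annotation does not name. The other Dppa4 probes, which start at bases 1133 and 1323, gave 89.4 ± 7.85 and 92.4 ± 1.20 units in the Dppa4 group against 88.1 ± 6.72 and 91.5 ± 1.41 in vector, and were above background on no array. The Myc probe at base 1189 gave 106 ± 1.27 units in vector, 146 ± 12.9 in Dppa4, 160 ± 17.8 in cMyc and 137 ± 38.2 in SV40. Its log2 fold change against vector was 1.58 ± 0.46 in cMyc (adjusted p = 0.054), 1.23 ± 0.46 in Dppa4 (adjusted p = 0.078) and 1.18 ± 0.46 in SV40 (adjusted p = 0.1). None of these passed the threshold. At that probe cMyc replicate 2 (147 units) lay below Dppa4 replicate 1 (155) and SV40 replicate 1 (164). The other Myc probe, at base 2203, was at background in all 4 groups. The Myc probes thus did not show the cMyc transgene. No probe for an SV40 gene was used here.

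**Figure D1:**
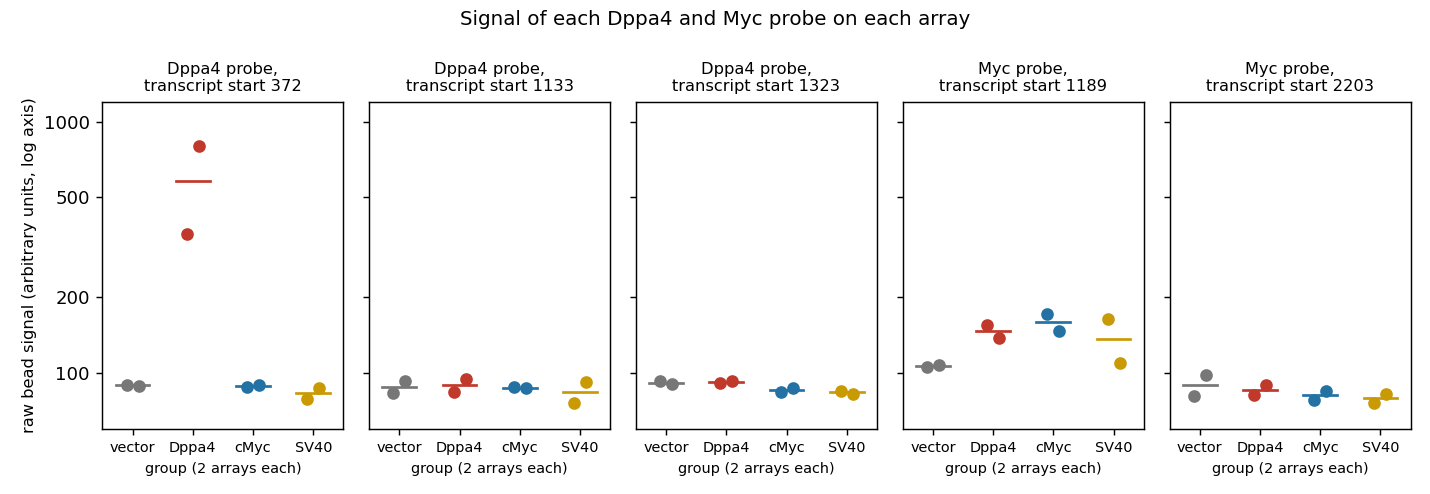
Raw bead signal (arbitrary units, log axis) of each Dppa4 and Myc probe on each array, by group. Points are single arrays and lines are group means; at the Dppa4 probe that starts at base 372 the Dppa4 arrays reached 356 and 800 units, while the vector arrays lay at 89.8 and 89.1.

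The comparison of Dppa4 foci with vector cells asks how cells that formed foci under Dppa4 differ from cells that carry the vector alone. In the Dppa4 group, the lists of mitosis, DNA replication and amino acid and endoplasmic reticulum stress were shifted up. Those of the extracellular matrix, inflammation, TGF-beta and BMP, and Wnt targets and components were shifted down. These are shifts by camera with its preset correlation that not every member shared, and 0 of them held with an estimated correlation. Beside Dppa4 itself, the largest increases were in Gch1, the first enzyme of tetrahydrobiopterin synthesis (4.40 ± 0.22, adjusted p = 3.2e-06), and Trib3, a pseudokinase induced by ATF4 (4.28 ± 0.64, 0.0012). They were followed by Ankrd1 (4.03 ± 0.49, 0.00039), Mgarp (3.63 ± 0.27, 3.3e-05) and Ccn2 (3.63 ± 0.57, 0.0015). Gch1 and Mgarp were above background on 1 of the 2 vector arrays, so the sizes of their increases are uncertain. Ppp1r1b was at least 9.65-fold higher (adjusted p = 0.0029), a call that ended without background correction, with the authors' normalized values and without vector replicate 2. Aox3, an aldehyde oxidase gene, was at least 9.80-fold higher (0.0045), with the Dppa4 arrays apart at 9.30 and 6.52, and its call ended without either vector array. Of the decreases, C3, the central complement protein, fell by 6.23 ± 0.84 on the log2 scale (adjusted p = 0.00072), the growth factor gene Igf2 by 6.19 ± 0.79 (0.00053) and the lipid phosphatase gene Plpp3 by 5.93 ± 0.29 (3.2e-06). Apod fell by 5.65 ± 0.67 (0.00037) and the chemokine gene Cxcl12 by 5.35 ± 0.37 (2.3e-05). Aoc3 was at least 54.8-fold lower, Scara5 at least 50.1-fold and Cyp2f2 at least 34.6-fold. The raw signal of Igf2 was 25560 ± 930 units in vector and 529 ± 383 in Dppa4 (SD, n = 2).

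Of the lists tested here, mitosis had the median furthest from 0. Of 33 measured genes of mitosis, 32 rose and 0 fell in Dppa4 (32 and 0 adjusted over the list alone), with a median log2 fold change of 1.76 (camera adjusted p = 1.3e-20). Among them were the kinase genes Aurka (2.52 ± 0.22, adjusted p = 6.8e-05) and Plk1 (2.31 ± 0.21, 9.1e-05), and Cdc20, an activator of the anaphase-promoting complex (2.40 ± 0.27, 0.00027). Of 38 genes of the G1/S step and DNA replication, 26 rose and 1 fell (31 and 1 adjusted over the list alone; median 1.07, adjusted p = 3.8e-11), among them Mcm10 (2.17 ± 0.25, 0.00032) and the thymidine kinase gene Tk1 (1.77 ± 0.22, 0.00044). In the list of Myc targets and ribosome biogenesis, 17 of 43 genes rose and 1 fell (20 and 1 adjusted over the list alone; median 0.65, adjusted p = 1.5e-06), led by Bcat1, an enzyme of branched-chain amino acid breakdown (2.83 ± 0.49, 0.0027). With an estimated correlation the adjusted p was 0.16 for mitosis, 0.21 for G1/S and 0.40 for the Myc list. The CDK inhibitor gene Cdkn1a rose in the same cells (2.35 ± 0.26, adjusted p = 0.00027), while Cdkn2c fell by 0.66 ± 0.22 (0.046), a call that ended with a replicate block and without any 1 of the vector or Dppa4 arrays. The list of CDK inhibitors and Rb family genes had 1 gene up and 1 down of 6 (adjusted p = 0.49).

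Of 36 genes in the list of amino acid and endoplasmic reticulum stress, 22 rose and 1 fell (23 and 2 adjusted over the list alone; median 1.11, camera adjusted p = 4.3e-07, or adjusted p = 0.33 with an estimated correlation). Trib3, Chac1, which degrades glutathione (3.44 ± 0.41, adjusted p = 0.00036), and the stress protein gene Nupr1 (3.27 ± 0.39, 0.00036) changed most. Of its 9 measured genes of endoplasmic reticulum chaperones and their regulators, a division made after the values were seen, 1 rose and 1 fell (median 0.36), and of the other 27, 21 rose and 0 fell (median 1.72). In glycolysis and hypoxia, 11 of 30 genes rose and 2 fell (13 and 2 adjusted over the list alone; median 0.52, adjusted p = 0.0049, or adjusted p = 0.23 with an estimated correlation). The phosphofructokinase gene Pfkp (3.22 ± 0.49, 0.0013) and Mif (2.30 ± 0.21, 8.4e-05) were among them. Cholesterol and fatty acid synthesis had 7 of 24 genes up and 0 down (median 0.33, adjusted p = 0.014, or adjusted p = 0.50 with an estimated correlation). The mevalonate pathway gene Mvd rose (1.55 ± 0.25, 0.002). In the list of MAPK output and EGF ligands, 7 of 19 genes rose and 0 fell (9 and 1 adjusted over the list alone; median 0.57, adjusted p = 0.0046, or adjusted p = 0.27 with an estimated correlation). They were led by the MAPK phosphatase gene Dusp4 (2.65 ± 0.30, 0.00027), the transcription factor gene Etv4 (2.13 ± 0.29, 0.00075) and Il11 (1.66 ± 0.20, 0.00036).

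Of 43 genes of collagens and matrix, 23 fell and 4 rose in Dppa4 (26 and 4 adjusted over the list alone; median -0.99, camera adjusted p = 1.1e-07, or adjusted p = 0.21 with an estimated correlation). The proteoglycan gene Lum fell by 4.80 ± 0.33 (adjusted p = 2.1e-05) and the fibrillar collagen gene Col3a1 decreased by 3.69 ± 0.28 (3.4e-05). The elastin gene Eln was at least 9.998-fold lower (0.015), a call that ended without any 1 of the vector or Dppa4 arrays, with no background correction, an offset of 50, the authors' values or no probe filter, and with eBayes trend and robust. Matrix metalloproteases and their inhibitors had 9 of 19 genes down and 1 up (median -0.66, adjusted p = 0.0023, or adjusted p = 0.21 with an estimated correlation). The inhibitor gene Timp4 was at least 33.0-fold lower, Timp3 fell by 3.44 ± 0.36 (0.00019) and Mmp9 fell by 3.05 ± 0.32 (0.00019). Apod, C3 and Mmp9 were above background on 1 of the 2 Dppa4 arrays, so the sizes of their falls are uncertain. In TGF-beta and BMP signalling, 12 of 20 genes fell and 5 rose (median -1.22, adjusted p = 0.014, or adjusted p = 0.32 with an estimated correlation). Id1, a BMP target, stood at -2.48 ± 0.36 (0.0011) and the receptor gene Tgfbr1 at -2.17 ± 0.28 (0.00063). Of 10 Wnt targets and components, 6 fell and 0 rose (median -0.87, adjusted p = 0.0049, or adjusted p = 0.21 with an estimated correlation). The secreted inhibitor gene Sfrp1 was among them (-3.25 ± 0.28, 6.4e-05), so the shift of this list does not show that Wnt signalling fell. Imprinted genes had 5 of 12 down and 1 up (median -0.76, adjusted p = 0.0036, or adjusted p = 0.23 with an estimated correlation). Igf2, H19 (-3.88 ± 0.74, 0.0043) and Dlk1 (-2.57 ± 0.22, 6.4e-05) changed most. The contractile and actin cytoskeleton list had a median of -0.24 and a mean of 0.01 (adjusted p = 0.61).

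In chemokines and inflammation, 9 of 24 genes fell and 2 rose (median -0.64, camera adjusted p = 0.016, or adjusted p = 0.28 with an estimated correlation). In the interferon response 14 of 31 fell and 3 rose (median -0.60, adjusted p = 0.0046, or adjusted p = 0.40 with an estimated correlation). The guanylate-binding protein gene Gbp2 fell by 3.01 ± 0.45 (adjusted p = 0.0012) and Samd9l by 2.47 ± 0.33 (0.00069). Lysosome and autophagy genes had 12 of 30 down and 1 up (median -0.55, adjusted p = 0.00064, or adjusted p = 0.40 with an estimated correlation). The membrane protein gene Lamp2 was among them (-1.93 ± 0.29, 0.0013). Of 9 measured pluripotency genes, Dppa4, Klf5 (1.70 ± 0.25, 0.0012) and Dnmt3b (0.93 ± 0.22, 0.012) rose and 0 fell (median 0.51, adjusted p = 0.02, or adjusted p = 0.23 with an estimated correlation). The transgene is 1 of these 3, and its rise was set by the design. The list was not tested without it, so its p-value does not show a shift of the other genes. The call for Dnmt3b ended without vector replicate 1, without either Dppa4 array and with a 2-fold minimum. Markers of other cell types moved in both directions: the haemoglobin gene Hba-a1 was at least 5.46-fold higher in Dppa4 (0.0018), the endothelial receptor gene Flt1 rose (2.87 ± 0.30, 0.00019), and the adipocyte lipase gene Lpl fell by 2.24 ± 0.22 (0.00015).

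By limma, 1094 genes were higher and 1037 lower in Dppa4 than in vector at an adjusted p under 0.05, 2131 in all (26.0% of 8208), and 1299 of them changed at least 2-fold. Camera with its preset correlation called 19 of 33 lists tested, and with an estimated correlation 0, with 6 at an unadjusted p under 0.05. Fry, which asks whether a list's genes move one way on balance without comparing them with other genes, called 21. The count was 742 without vector replicate 1, 730 without vector replicate 2, 1009 without Dppa4 replicate 1 and 1011 without Dppa4 replicate 2, each fit with a lone array assumed to vary like the other groups. Of the 97 genes that the naming rule chose here, 24, 25, 16 and 18 then missed the threshold and 0 turned direction.

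The comparison of cMyc foci with vector cells puts a known oncogene beside the same control. The lists of ribosome biogenesis, oxidative phosphorylation and mitosis were shifted up in cMyc, and those of MAPK output, the cytoskeleton, the matrix and inflammation down. In several of them most members did not pass on their own, and 0 of these shifts held with an estimated correlation. The largest increases were in Ppp1r1b, at least 15.7-fold higher (adjusted p = 0.0034), the dCTP pyrophosphatase gene Dctpp1 (2.32 ± 0.29, 0.0018), Ddit4, an inhibitor of mTOR complex 1 (2.11 ± 0.38, 0.0075), and Ckmt1, a mitochondrial creatine kinase (2.09 ± 0.54, 0.034). Next came Mfap4 (2.01 ± 0.28, 0.0027), the folate carrier gene Slc19a1 (2.00 ± 0.31, 0.004), Srpx2 (1.94 ± 0.29, 0.0035) and Cdc20 (1.93 ± 0.27, 0.0027). Ppp1r1b lay at 7.29 and 9.90 on the cMyc arrays, so its fold depends on the array, and its call ended without either vector array. The call for Ckmt1 ended under several settings, among them a fit of these groups alone. Those for Ddit4, Slc19a1, Srpx2 and Cdc20 ended without either vector array, and that for Ddit4 without cMyc replicate 1 as well. Those for Dctpp1 and Mfap4 ended without vector replicate 2. Of the decreases, Prl2c3 fell by 6.19 ± 0.58 (0.00053) and Mrpplf3 by 6.10 ± 0.61 (0.00055), close relatives in the prolactin family whose probes may read each other's transcripts. Sfrp1 fell by 4.92 ± 0.28 (4.8e-05), the chemokine gene Ccl7 by 4.38 ± 0.60 (0.0025), Apod by 4.37 ± 0.67 (0.0037), Cyp2f2 by 4.31 ± 0.58 (0.0024), C3 by 3.90 ± 0.84 (0.017) and Timp4 by 3.87 ± 0.72 (0.0088). The call for C3, at 5.07 and 8.69 on the cMyc arrays, ended without the probe filter, with eBayes trend and robust, in a fit of these groups alone and without any 1 of the vector or Dppa4 arrays. The calls for Ccl7, Apod, Cyp2f2 and Timp4 ended without either vector array, and that for Timp4 without the probe filter as well. Mrpplf3, Sfrp1, Ccl7, Cyp2f2 and Timp4 were above background on 1 of the 2 cMyc arrays, so the sizes of their falls are uncertain. Ccl7 lay at 4.57 and 6.77 on these arrays and Timp4 at 4.31 and 7.39.

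Myc targets and ribosome biogenesis had 28 of 43 genes up and 0 down in cMyc (37 and 0 adjusted over the list alone), with a median log2 fold change of 1.03 (camera adjusted p = 1.6e-16). Slc19a1, Noc4l (1.64 ± 0.25, adjusted p = 0.0036) and Mrto4 (1.63 ± 0.29, 0.0075), the latter pair factors of ribosome assembly, rose most. In mitosis 22 of 33 genes rose and 0 fell (29 and 0 adjusted over the list alone; median 1.25, adjusted p = 4.7e-17), and in G1/S and DNA replication 14 of 38 rose and 2 fell (23 and 2 adjusted over the list alone; median 0.75, adjusted p = 2.7e-07). Bub1b (1.67 ± 0.26, 0.0037) and the replication gene Mcm5 (1.49 ± 0.21, 0.0029) were among them. Oxidative phosphorylation had 8 of 55 genes up and 0 down (10 and 0 adjusted over the list alone; median 0.49, adjusted p = 8.7e-08), with the ATP synthase gene Atp5o at 1.26 ± 0.22 (0.0065). Ribosomal proteins had 6 of 42 up and 0 down (median 0.42, adjusted p = 1.2e-05), with Rplp0 at 1.68 ± 0.25 (0.0035). With an estimated correlation the adjusted p was 0.17 for the Myc list, 0.073 for mitosis, 0.11 for G1/S, 0.11 for oxidative phosphorylation and 0.27 for ribosomal proteins. The list of amino acid and endoplasmic reticulum stress had 1 gene up and 2 down of 36 (median -0.04, adjusted p = 0.85). That gene was Psat1, an enzyme of serine synthesis (1.15 ± 0.32, 0.044). Its call ended under each other normalization, without the probe filter and without any 1 of the vector, Dppa4 or cMyc arrays, and adjusted over the list alone 0 genes of the list rose.

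Of 19 genes of MAPK output and EGF ligands, 11 fell and 0 rose in cMyc (11 and 0 adjusted over the list alone; median -0.80, camera adjusted p = 3.6e-08, or adjusted p = 0.089 with an estimated correlation). The phosphatase gene Dusp6 fell by 3.66 ± 0.39 (adjusted p = 0.00075), Phlda1 by 2.08 ± 0.35 (0.006) and the cyclin gene Ccnd1 by 1.78 ± 0.20 (0.00095). Immediate early and heat shock genes had 4 of 14 down and 0 up (median -0.51, adjusted p = 0.004, or adjusted p = 0.19 with an estimated correlation). The transcription factor gene Egr2 was among them (-2.32 ± 0.23, 0.00053). In the contractile and actin cytoskeleton list 8 of 30 fell and 0 rose (14 and 0 adjusted over the list alone; median -0.69, adjusted p = 8.9e-06, or adjusted p = 0.11 with an estimated correlation). The focal adhesion genes Vcl and Zyx stood at -1.32 ± 0.26 (0.012) and -1.30 ± 0.21 (0.0048). Collagens and matrix had 14 of 43 genes down and 1 up (18 and 1 adjusted over the list alone; median -0.55, adjusted p = 2.7e-07, or adjusted p = 0.11 with an estimated correlation). They were led by the basement membrane gene Nid1 (-3.01 ± 0.23, 0.00033) and Col3a1 (-2.97 ± 0.28, 0.00053). Chemokines and inflammation had 11 of 24 down and 0 up (15 and 1 adjusted over the list alone; median -0.94, adjusted p = 2e-08, or adjusted p = 0.073 with an estimated correlation). Il1rl1, which encodes the interleukin-33 receptor, fell by 3.30 ± 0.32 (0.00053). The IGF axis had 3 of 11 genes down and 0 up (median -0.67, adjusted p = 0.0011, or adjusted p = 0.11 with an estimated correlation). Igf1 was among them (-3.31 ± 0.25, 0.00033). Of 29 p53 targets, 5 fell and 1 rose; the list's median was 0.12 and its mean -0.13 (adjusted p = 0.86).

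By limma, 464 genes were higher and 499 lower in cMyc than in vector, 963 in all (11.7% of 8208), and 652 of them changed at least 2-fold. Camera called 18 of 33 lists with its preset correlation and 0 with an estimated one, with 12 at an unadjusted p under 0.05, and fry called 19. The direction split depended on the scaling, at 265 higher and 655 lower with median scaling and 362 and 608 with cyclic loess, where the median of all genes lay at -0.12 and -0.01. The count was 78 without vector replicate 1, 58 without vector replicate 2, 533 without cMyc replicate 1, 587 without Dppa4 replicate 1 and 589 without Dppa4 replicate 2, and 1448 with array weights. Of the 87 genes that the naming rule chose here, 64 and 68 missed the threshold without 1 of the vector arrays, 17 to 19 without a cMyc or Dppa4 array, and 0 turned direction.

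The comparison of SV40 foci with vector cells gives the second reference oncogene. The lists of DNA replication, mitosis and amino acid and endoplasmic reticulum stress were shifted up in SV40, and those of the matrix, TGF-beta and BMP signalling and oxidative stress down. Not every member shared these shifts, and 0 of them held with an estimated correlation. Trib3 rose most (4.34 ± 0.64, adjusted p = 0.0016), followed by Gask1b, a Golgi kinase homolog (3.79 ± 0.25, 1.8e-05), Fam110c (3.79 ± 0.21, 8.5e-06), Chac1 (3.46 ± 0.41, 0.00053) and Ccn2 (3.19 ± 0.57, 0.004). Further increases were in Nupr1 (3.11 ± 0.39, 0.00068), Raet1b, a ligand of the activating receptor NKG2D (2.85 ± 0.36, 0.00071), and the replication licensing gene Cdt1 (2.82 ± 0.25, 0.00019). Lum fell by 6.10 ± 0.33 (8.5e-06), Gas6, a ligand of TAM receptor kinases, fell by 5.88 ± 0.43 (3.4e-05) and Cxcl12 fell by 5.24 ± 0.37 (3e-05). Apod was at least 55.1-fold lower, Scara5 at least 49.5-fold, Timp4 at least 32.7-fold, Sfrp1 at least 31.7-fold and the carboxylesterase gene Ces1d at least 24.8-fold. The call for Ccn2 ended without either vector array, and that for Scara5 without vector replicate 2.

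Of 38 genes of the G1/S step and DNA replication, 29 rose and 2 fell in SV40 (32 and 2 adjusted over the list alone; median 1.68, camera adjusted p = 3.6e-17), among them Cdt1, the helicase gene Mcm2 (2.67 ± 0.25, adjusted p = 0.00022) and the ligase gene Lig1 (2.35 ± 0.29, 6e-04). Mitosis had 30 of 33 genes up and 0 down (32 and 0 adjusted over the list alone; median 1.75, adjusted p = 2.6e-22), with the spindle checkpoint gene Mad2l1 at 2.29 ± 0.24 (0.00029). Chromatin modifiers had 5 of 20 up and 0 down (8 and 0 adjusted over the list alone; median 0.20, adjusted p = 0.034), led by Uhrf1 (1.77 ± 0.21, 0.00053) and the maintenance DNA methyltransferase gene Dnmt1 (1.71 ± 0.24, 0.0011). In the Myc list 14 of 43 rose and 0 fell (23 and 1 adjusted over the list alone, median 0.68, adjusted p = 1.1e-06). Its median against vector was 0.88 on SV40 replicate 1 and 0.36 on SV40 replicate 2. With an estimated correlation the adjusted p was 0.11 for G1/S, 0.11 for mitosis, 0.27 for chromatin modifiers and 0.42 for the Myc list. Amino acid and endoplasmic reticulum stress had 19 of 36 genes up and 2 down (21 and 2 adjusted over the list alone; median 1.27, adjusted p = 1.6e-07, or adjusted p = 0.33 with an estimated correlation). The list's median against vector was 1.69 on SV40 replicate 1 and 0.71 on SV40 replicate 2. The Rb family gene Rbl1 rose (1.49 ± 0.28, 0.0055). Of 29 p53 targets, 9 fell and 4 rose (11 and 6 adjusted over the list alone; median -0.21, adjusted p = 0.18), with Phlda3 at -2.59 ± 0.26 (0.00025) and the death receptor gene Fas at -2.31 ± 0.30 (0.00086).

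Collagens and matrix had 23 of 43 genes down and 2 up in SV40 (29 and 2 adjusted over the list alone; median -0.93, camera adjusted p = 1.5e-09, or adjusted p = 0.20 with an estimated correlation). Nid2 fell by 2.96 ± 0.28 (adjusted p = 0.00022). Oxidative stress and glutathione genes had 12 of 26 down and 3 up (14 and 5 adjusted over the list alone; median -0.69, adjusted p = 0.042, or adjusted p = 0.52 with an estimated correlation). The epoxide hydrolase gene Ephx1 was among them (-2.59 ± 0.30, 0.00048). TGF-beta and BMP signalling had 10 of 20 down and 2 up (median -1.05, adjusted p = 0.0039, or adjusted p = 0.27 with an estimated correlation). Id1 stood at -2.24 ± 0.36 (0.0026). Of 7 Notch genes, 2 fell and 0 rose (median -0.65, adjusted p = 0.018, or adjusted p = 0.27 with an estimated correlation). They were Dlk1, which is imprinted as well (-1.62 ± 0.22, 9e-04), and Notch1, at least 1.68-fold lower (0.0087). Imprinted genes had 4 of 12 down and 0 up (median -0.41, adjusted p = 0.016, or adjusted p = 0.27 with an estimated correlation). Their median against vector was -0.85 on SV40 replicate 1 and -0.24 on SV40 replicate 2. Igf2 fell by 4.99 ± 0.79 (0.0022). The haematopoietic marker Lyz2 was at least 3.30-fold lower (0.00024) and Cd14 rose (1.62 ± 0.32, 0.0068), with a signal above background on 1 of the 2 vector arrays. That list had 1 of 7 up and 1 down, with a median of 0.14 and a mean of -0.12 (adjusted p = 0.67). Genes of chromosomes 12, 18 and 3 had medians of 0.31, 0.28 and 0.21 in this comparison, and those of chromosome 1 a median of -0.18.

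By limma, 761 genes were higher and 812 lower in SV40 than in vector, 1573 in all (19.2% of 8208), and 1049 of them changed at least 2-fold. Camera called 17 of 33 lists with its preset correlation and 0 with an estimated one, with 6 at an unadjusted p under 0.05, and fry called 15. With median scaling, which put the median of all genes at -0.24, 394 genes were higher and 1402 lower. The count was 442 without vector replicate 1 and 435 without vector replicate 2. Of the 88 genes that the naming rule chose here, 30 and 33 then missed the threshold, 13 did so without either SV40 array, and 0 turned direction. At 6 genes (Irgm1, Mid1, Nme7, Srrm2, Tmsb10 and Vmp1) 2 probes were called in opposite directions.

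**Figure D2:**
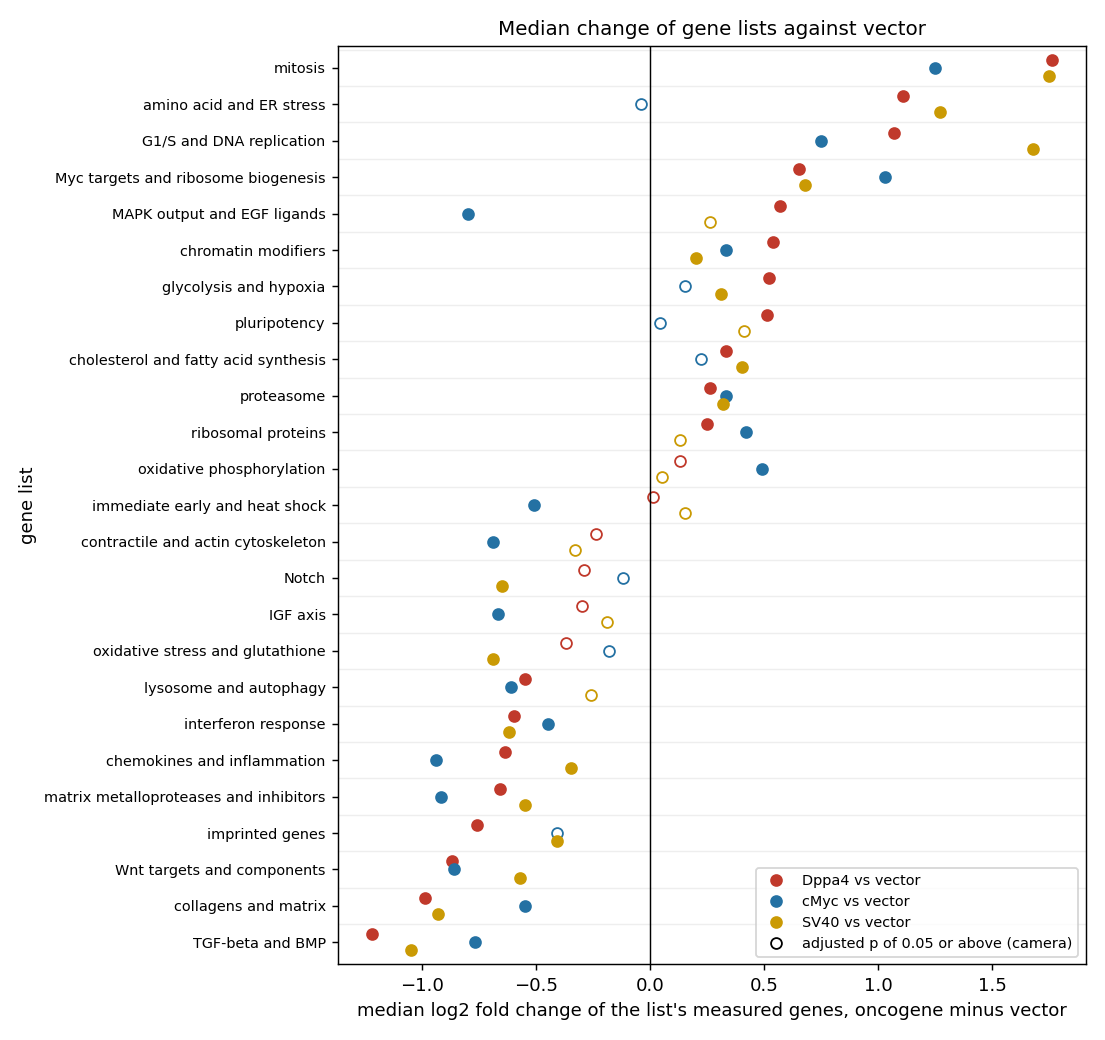
Median log2 fold change against vector (horizontal axis) of each gene list that camera called in at least 1 of the 3 contrasts (vertical axis), with filled points where the adjusted p with the preset correlation was under 0.05. Mitosis lay at 1.76, 1.25 and 1.75 in Dppa4, cMyc and SV40, and MAPK output and EGF ligands at 0.57, -0.80 and 0.26; no list was called with an estimated correlation.

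The 3 contrasts share the vector arrays, and the overlap between them shows which differences from those arrays the foci had in common. The growth state of the vector cultures enters all 3 contrasts, so it cannot be told apart from changes common to the foci. This holds for the lists of mitosis and DNA replication too. In all 3, 193 genes were higher and 210 lower, 403 together, where independent contrasts would give 5.73 and 6.24. The shared vector arrays can raise this overlap, by an amount that was not tested. Shared increases were Ddit4 (2.37 ± 0.38 in Dppa4, 2.11 ± 0.38 in cMyc and 2.50 ± 0.38 in SV40), Dctpp1 (2.28, 2.32 and 1.89, each ± 0.29), Sap30, a subunit of a histone deacetylase complex (3.06, 1.77 and 2.71, each ± 0.27), and Cdc20 (2.40, 1.93 and 1.75, each ± 0.27). The histone genes H2ac10 (1.99, 1.80 and 2.04, each ± 0.27) and H2ac22 (2.08, 1.71 and 2.00, each ± 0.27) rose as well, although their probes may read the transcripts of near-identical copies. Shared decreases were Apod, Cyp2f2, C3, Timp4 and Scara5, a receptor for ferritin, which in cMyc fell by 3.49 ± 0.99 (adjusted p = 0.047), and Sfrp1. Of these 12 genes, Sfrp1 kept its call in cMyc without each array in turn, and each of the others lost it without at least 1 of the vector arrays. The calls for Scara5, C3 and Timp4 in cMyc ended without the probe filter as well. That for Scara5 also ended with no background correction, an offset of 50, cyclic loess, the authors' values, and eBayes with trend and robust. It ended too in a fit of cMyc and vector alone and without any 1 of the vector, Dppa4 or SV40 arrays. Scara5 lay at 4.67 and 9 on the cMyc arrays, above background on 1 of them.

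Among the 193 shared increases, 21 of the 33 measured mitosis genes appeared where 0.776 would be drawn by chance (Fisher's exact test, one-sided, adjusted p = 3.8e-25 over the lists and directions), with Aurka, Cdc20, Mad2l1 and Plk1 among them. G1/S and DNA replication gave 14 of 38 (expected 0.894, adjusted p = 1.9e-12), Lig1, Mcm2 and Tk1 included, and Myc targets gave 8 of 43 (expected 1.01, adjusted p = 0.00013). Among the shared decreases, collagens and matrix gave 7 of 43 (expected 1.10, adjusted p = 0.0013): Col3a1, Col6a1, Dcn, Has2, Lum, Mfap5 and Nid1. Wnt targets and components gave 4 of 10 (expected 0.256, adjusted p = 0.0013): Ccn5, Dkk3, Fzd2 and Sfrp1. Chemokines and inflammation gave 5 of 24 (expected 0.614, adjusted p = 0.0033), and TGF-beta and BMP 4 of 20 (expected 0.512, adjusted p = 0.012), with the receptor genes Tgfbr1, Tgfbr2 and Tgfbr3. Genes within a list are not independent, so these p-values are lower than the evidence warrants.

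Taken in pairs, Dppa4 and SV40 shared 519 increases (101 expected of independent contrasts) and 564 decreases (103 expected), and 7 genes moved in opposite directions. Dppa4 and cMyc shared 279 increases (61.8 expected) and 269 decreases (63.04 expected), and 45 genes moved in opposite directions, 38 of them higher in Dppa4. The fold changes of Dppa4 and SV40 correlated at r = 0.80 across genes, those of Dppa4 and cMyc at 0.55 and those of cMyc and SV40 at 0.57, where groups without changes that share the control gave 0.50. The covariances were 0.517, 0.302 and 0.281, against 0.045 in such groups. The simulated groups all had the same spread per gene, whereas the real arrays differed least in vector. The SD of the difference between arrays was 0.253 in vector, 0.366 in Dppa4, 0.504 in cMyc and 0.521 in SV40. A control that varies less adds less to both measures, so 0.50 and 0.045 can be too high for these data. The shared count was 46 without vector replicate 1, 36 without vector replicate 2, 216 and 223 without Dppa4 replicates 1 and 2, 228 without cMyc replicate 1, 258 with a 2-fold minimum and 610 with array weights.

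The direct comparison of Dppa4 with cMyc shows where these foci differed from each other. MAPK output and EGF ligands had 15 of 19 genes higher in Dppa4 and 0 lower (17 and 0 adjusted over the list alone; median 1.31, camera adjusted p = 1.7e-12, or adjusted p = 0.19 with an estimated correlation). Amino acid and endoplasmic reticulum stress had 16 of 36 higher and 0 lower (25 and 0 adjusted over the list alone; median 0.92, adjusted p = 5.1e-11, or adjusted p = 0.34 with an estimated correlation). Il1rl1 was 5.73 ± 0.32 higher on the log2 scale in Dppa4 (adjusted p = 1.1e-05), Prl2c3 5.14 ± 0.58 (0.00036), Mrpplf3 5.05 ± 0.61 (5e-04), Ccl7 4.86 ± 0.60 (0.00058) and Tes, a focal adhesion protein gene, 4.82 ± 0.38 (4.8e-05). Mrpplf3 and Ccl7 were above background on 1 of the 2 cMyc arrays, so the sizes of their differences are uncertain. On the other side, the heparin-binding growth factor gene Ptn was lower in Dppa4 (-4.65 ± 0.26, 1.1e-05), as was the pentraxin gene Ptx3 (-5.00 ± 0.74, 0.0016). Wfdc12 was at least 29.8-fold lower, Eln at least 19.2-fold and Aoc3 at least 16.4-fold. The raw signal of Eln in cMyc was 1215 ± 1464 units (SD, n = 2), and its call ended without either Dppa4 array, with no background correction, the authors' values or no probe filter, and with eBayes trend and robust. Oxidative phosphorylation had 2 of 55 genes lower in Dppa4 and 0 higher (median -0.32, adjusted p = 0.0055, or adjusted p = 0.34 with an estimated correlation). In all, 693 genes were higher and 563 lower in Dppa4 than in cMyc. Camera called 11 of 33 lists with its preset correlation and 0 with an estimated one. This count of 1256 became 751 and 746 without vector replicates 1 and 2, 516 and 414 without Dppa4 replicates 1 and 2, and 749 without cMyc replicate 2.

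Dppa4 and SV40 differed at 201 genes higher and 114 lower in Dppa4, the fewest of the 6 contrasts with all 8 arrays but not without either vector array. Dppa4 itself was at least 17.2-fold higher, Ppp1r1b at least 9.17-fold, Gch1 higher by a log2 fold change of 3.33 ± 0.22 (adjusted p = 2e-04), Aox3 of 3.29 ± 0.66 (0.026) and Clu, an extracellular chaperone gene, of 3.11 ± 0.31 (0.001). The water channel gene Aqp1 was lower in Dppa4 (-3.26 ± 0.57, 0.015), as were Thbs2 (-2.68 ± 0.37, 0.0055), Smoc1 (-2.67 ± 0.52, 0.021) and the matrix Gla protein gene Mgp (-2.54 ± 0.33, 0.0041), and P2ry14 was at least 5.01-fold lower. Of 29 p53 targets, 5 were higher in Dppa4 and 0 lower (7 and 1 adjusted over the list alone; median 0.33, camera adjusted p = 4e-04, or adjusted p = 0.27 with an estimated correlation). Of 38 genes of G1/S and DNA replication, 4 were lower and 1 higher (12 and 2 adjusted over the list alone; median -0.44, adjusted p = 4e-04, or adjusted p = 0.56 with an estimated correlation). MAPK output and EGF ligands had 3 of 19 higher and 0 lower (6 and 0 adjusted over the list alone; median 0.41, adjusted p = 0.00042, or adjusted p = 0.56 with an estimated correlation). Lysosome and autophagy genes had 1 of 30 lower and 0 higher (6 and 0 adjusted over the list alone, median -0.46, adjusted p = 0.0063, or adjusted p = 0.71 with an estimated correlation). Against vector this list's median was -0.49 and -0.72 on the Dppa4 arrays. It was -0.43 on SV40 replicate 1 and 0.03 on SV40 replicate 2, so the difference depends on the SV40 array. The count of 315 fell to 31 and 32 without Dppa4 replicates 2 and 1, 93 and 90 without vector replicates 1 and 2, 157 without SV40 replicate 2 and 149 in a fit of these groups alone, and reached 493 without SV40 replicate 1. Of the 10 genes that the naming rule chose here, 7 missed the threshold without some array. The calls for Ppp1r1b, Aox3, Aqp1 and Smoc1 ended without the probe filter as well. Those for Ppp1r1b, Aox3 and Smoc1 also ended under each of no background correction, an offset of 50 and the authors' values. Those for Aox3 and Aqp1 ended with eBayes trend and robust, and that for Aox3 in a fit of these groups alone. Aox3 was above background on 1 of the 2 SV40 arrays. With median scaling, which moved the median of all genes to 0.14, 331 genes were higher and 50 lower, and among probes with a detection p under 0.01 on all 8 arrays, 131 and 113.

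cMyc and SV40 differed at 448 genes higher and 502 lower in cMyc. Wfdc12 was higher in cMyc (4.49 ± 0.50, adjusted p = 0.00065), as were Lum (4.25 ± 0.33, 9.6e-05), Ppp1r1b, at least 14.9-fold, Eln, at least 18.9-fold, and the microfibril gene Mfap4, at least 11.8-fold. Il1rl1 (-5.55 ± 0.32, 2.7e-05), Trib3 (-4.29 ± 0.64, 0.0029), the stress gene Gadd45a (-4.06 ± 0.52, 0.0012) and Gask1b (-4.06 ± 0.25, 3.4e-05) were lower, and Fam110c was at least 16.1-fold lower. G1/S and DNA replication had 18 of 38 genes lower in cMyc and 0 higher (28 and 1 adjusted over the list alone; median -0.86, camera adjusted p = 1.6e-11, or adjusted p = 0.22 with an estimated correlation). Amino acid and endoplasmic reticulum stress had 11 of 36 lower and 0 higher (24 and 0 adjusted over the list alone; median -1.01, adjusted p = 1e-11, or adjusted p = 0.36 with an estimated correlation). Oxidative phosphorylation had 9 of 55 higher and 0 lower (13 and 0 adjusted over the list alone; median 0.40, adjusted p = 9.6e-07, or adjusted p = 0.36 with an estimated correlation). Camera called 9 of 33 lists here and 0 with an estimated correlation. The call for Eln ended without any 1 of the vector or SV40 arrays, with no background correction, an offset of 50, the authors' values or no probe filter, with eBayes trend and robust, and in a fit of these groups alone. The count of 950 became 480 and 464 without vector replicates 1 and 2, 479 without cMyc replicate 2, 201 in a fit of these groups alone and 494 with array weights. With median scaling, which moved the median of all genes to 0.13, 529 genes were higher and 339 lower.

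**Figure D3:**
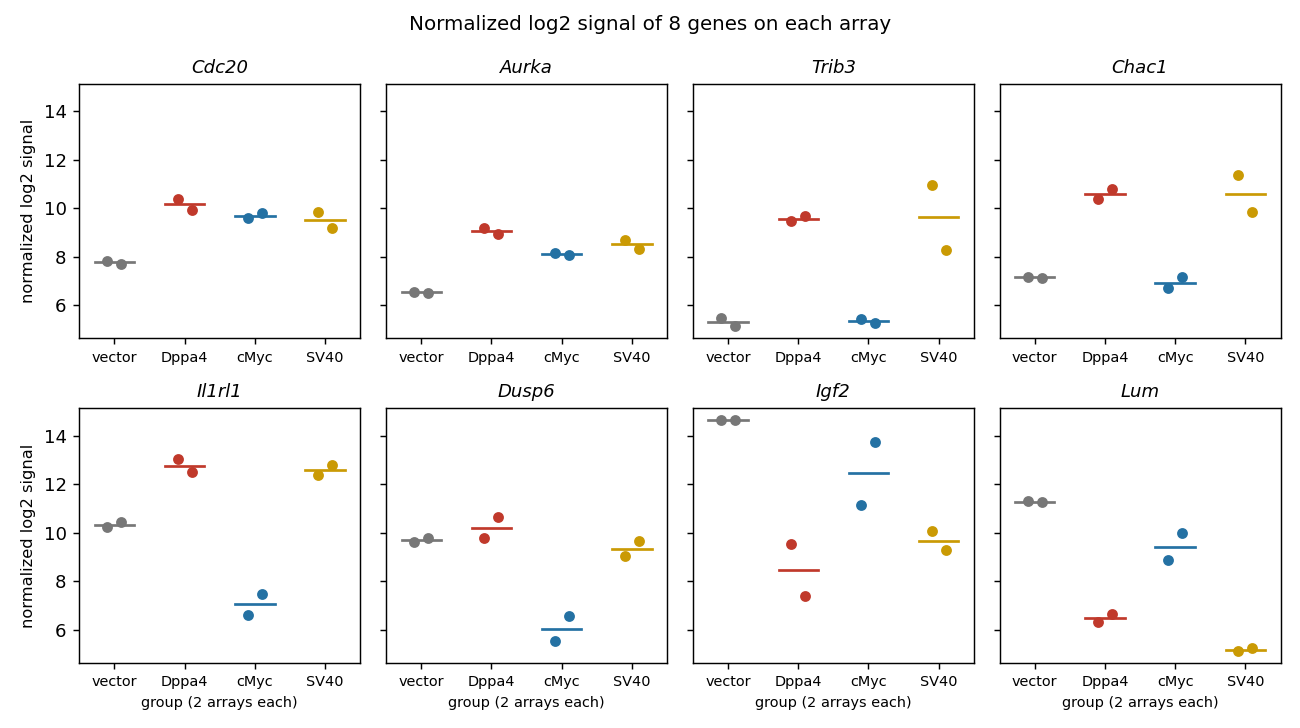
Normalized log2 signal (vertical axis) of 8 genes on each array, by group, with points for single arrays and lines for group means. Il1rl1 lay at 10.24 and 10.45 in vector, 13.05 and 12.5 in Dppa4 and 6.61 and 7.49 in cMyc, and Trib3 at 10.98 and 8.27 on the SV40 arrays.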

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

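Of the tests in this part, the median difference between the vector arrays was set before its result was seen, and the other tests were chosen after the results they concern.

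Gadd45a, Il1rl1, Mfap4 and Tes changed in opposite directions against vector in cMyc and in another oncogene group, and the direct contrast passed the threshold. Il1rl1 was higher in Dppa4 (2.43 ± 0.32) and SV40 (2.25 ± 0.32) and lower in cMyc (-3.30 ± 0.32), a difference of 5.73 for Dppa4 against cMyc and -5.55 for cMyc against SV40. Gadd45a was at 2.27 ± 0.52 in Dppa4, 1.68 ± 0.52 in SV40 and -2.38 ± 0.52 in cMyc, with differences of 4.65 and -4.06. Its call in cMyc against vector ended without background correction, with an offset of 50, with the authors' values, without the probe filter and without any 1 of the vector, Dppa4 or cMyc arrays. Mfap4 moved the other way, at 2.01 ± 0.28 in cMyc, and was not above background in Dppa4 and SV40. It was thus at least 2.95-fold lower in Dppa4 and at least 2.92-fold lower in SV40 than in vector, and the model values of -3.89 and 3.82 for the direct contrasts stand for at least 11.9-fold and at least 11.8-fold. Tes differed by 4.82 between Dppa4 (2.51 ± 0.38) and cMyc (-2.32 ± 0.38). The list of MAPK output and EGF ligands was called higher in Dppa4 and lower in cMyc, and its median in the direct contrast was 1.31; with an estimated correlation the adjusted p was 0.27, 0.089 and 0.19.

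The list of amino acid and endoplasmic reticulum stress was shifted up in Dppa4 and SV40 against vector, with 22 and 19 of 36 genes higher. Array scaling and background correction are argued against: over 5 other normalizations the lowest median of the list was 0.66, and the highest adjusted p 6.3e-06 with the preset correlation (adjusted p = 0.33 in each contrast with an estimated correlation). Unfolded proteins in the endoplasmic reticulum should raise its chaperones. The 9 measured genes of chaperones and their regulators had medians of 0.36 in Dppa4 and -0.03 in SV40. Their highest single values, 0.91 and 0.66, lay below the medians of 1.72 and 1.52 of the other 27 genes. Hspa5, Manf, Pdia6 and Sdf2l1 of the list were not among the genes tested. The values thus argue against unfolded proteins only for the 9 genes measured, by a division made after the values were seen. What also stays open is the state of the single cultures at harvest, since no label gives density or medium. The list's median differed by 0.98 between the SV40 arrays, but lay at 1.15 and 1.11 on the Dppa4 arrays. A response to amino acid shortage that depends on the oncogene is a hypothesis that was not tested. These data cannot separate it from culture conditions, nor fully from unfolded proteins.

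The list of collagens and matrix was shifted down in all 3 oncogene groups against vector, with 23, 14 and 23 of 43 genes lower in Dppa4, cMyc and SV40 and 7 lower in all 3. Array scaling and background correction are argued against: the median nearest to 0 over 5 other normalizations and the 3 contrasts was -0.49, with the highest adjusted p at 3.7e-06 with the preset correlation (adjusted p = 0.21, 0.11 and 0.20 with an estimated correlation). A difference between the vector arrays is argued against as well, since their median difference over the list was 0.07. The growth state of the vector cultures cannot be told apart from the oncogenes, because all 3 contrasts use the same 2 vector arrays. Between Dppa4 and cMyc, 17 of the 43 matrix genes differed as well. The vector cultures do not enter those fold changes, but their arrays enter the shared estimate of spread behind the calls.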

How the results depend on the processing

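The crossed replicate block was added after the data were seen; the other alternatives were planned. The count of Dppa4 against vector was 3317 in a fit of the compared groups alone, 3304 with array weights and 1299 with a 2-fold minimum. In a fit of the compared groups alone, Dppa4 against SV40 gave 149 and cMyc against SV40 201. Array weights gave 1448 for cMyc against vector, 494 for cMyc against SV40 and 610 for the genes shared by all 3, which a 2-fold minimum put at 258. The cause was not tested, except that a 2-fold minimum can only lower a count. The fit of all groups shares 1 estimate of spread per gene. The SD of the difference between the arrays of a group was 0.253 in vector, 0.366 in Dppa4, 0.504 in cMyc and 0.521 in SV40. Across genes, a shared estimate thus lies above the spread of vector and Dppa4 and below that of cMyc and SV40, which can move these counts. Leaving out single arrays gave 730 to 2521 genes for Dppa4 against vector, 58 to 1342 for cMyc against vector, 435 to 1767 for SV40 against vector, 414 to 1550 for Dppa4 against cMyc, 31 to 493 for Dppa4 against SV40, 464 to 964 for cMyc against SV40 and 36 to 543 for the shared genes. With a replicate block the counts were 2108, 938, 1545, 1237, 303 and 915. The labels do not say whether the replicate numbers pair the arrays. Deviations from the group means correlated at -0.13 to 0.09 between groups across genes. No strong shared effect of the numbers was thus seen, which does not show that the arrays were unpaired. With the numbers of the cMyc arrays crossed in the replicate block, Dppa4 against cMyc gave 1216. A block for the chip was not run, as no chip is given in the sources used here. Of 307 gene results, 155 kept their side of the threshold in every alternative that held the gene, and 237 in every such one that used 8 arrays. Direction was compared only where a gene was called, and 0 reversed. A detection p under 0.01 on all 8 arrays removed part of the genes and lists, which were not tried there. Of 198 list results, 85 and 94 kept their side of the threshold in this way. None of these had been called, since the 78 list results that were called lost their call with an estimated correlation. Amino acid and endoplasmic reticulum stress turned to -0.56 (adjusted p = 0.0026) for Dppa4 against SV40 without SV40 replicate 2 and was 0.53 (adjusted p = 7e-04) without SV40 replicate 1; the SV40 arrays differ on this list. No list kept its call with an estimated correlation. Signal over background limits the folds of genes under detection in 1 group, which are printed as lower bounds.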

Other observations

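Of the tests in this part, those of scaling and of signal level were set before their results were seen, and the test by stretches of a chromosome and the choice of histone genes and chromosomes came after.

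Histone genes were chosen after the values were seen and were not tested as a set. Of 41 measured, 22 were higher and 4 lower in Dppa4 than in vector (median 0.80), 15 and 3 in SV40 (median 0.51) and 11 and 2 in cMyc (median 0.24). Of the 29 in the cluster on chromosome 13, 19 were higher and 2 lower in Dppa4 (median 0.97), and 7 were higher and 0 lower in Dppa4 than in cMyc. H3c4 was at 1.81 ± 0.28 in Dppa4, 1.66 ± 0.28 in SV40 and 0.46 ± 0.28 in cMyc. The variant gene H2az1 was at 1.26 ± 0.22, 2.04 ± 0.22 and 1.45 ± 0.22 in Dppa4, SV40 and cMyc. The linker histone gene H1f2 fell by 1.65 ± 0.25 in Dppa4 and by 1.39 ± 0.25 in SV40. Near-identical copies share probe sequence, so single histone genes are uncertain.

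Of 51 homeobox and related genes in the list, 19 were measured; 3 rose and 5 fell in Dppa4 (median -0.22, adjusted p = 0.43). Meis1 fell by 1.73 ± 0.20 in Dppa4 (adjusted p = 0.00035). The proteasome list was called higher as a list in Dppa4, cMyc and SV40, with 2, 1 and 3 of its 27 measured genes higher and medians of 0.26, 0.33 and 0.32 (adjusted p = 0.036, 0.0039 and 0.016, or adjusted p = 0.23, 0.11 and 0.20 with an estimated correlation).

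Genes of chromosomes 12 and 18 were as sets shifted up in SV40 against vector, with medians of 0.31 over 261 genes and 0.28 over 194 (camera adjusted p = 0.0065 for each, or adjusted p = 0.65 and 0.72 with an estimated correlation), and 0 of 10000 sets of genes of like signal lay as far from 0. Chromosome 3 was called higher as well (median 0.21 over 395 genes, adjusted p = 0.03, or adjusted p = 0.22 with an estimated correlation), chromosome 1 had a median of -0.18 (adjusted p = 0.053), and for each 0 of 10000 sets lay as far. The drawn sets treat genes as independent, and these chromosomes were chosen after the values were seen, so the draws cannot exclude chance. Against vector, the medians of chromosomes 12 and 18 were 0.04 and 0.04 in Dppa4 and -0.05 and -0.06 in cMyc. Array scaling is argued against, since over 5 other normalizations the lowest median relative to all genes was 0.16. A few strongly changed genes are argued against, since 16 of 16 medians by stretch of chromosome (4 for each) and SV40 array lay above 0, from 0.09 to 0.42. Extra copies may explain the shift, since 6 of 6 medians of genes of low, middle and high signal lay above 0.1, but these were uneven, at 0.25, 0.29 and 0.43 for chromosome 12 and 0.11, 0.40 and 0.32 for chromosome 18, where a step from 2 copies to 3 would give 0.58, from 3 to 4 would give 0.42 and from 4 to 5 would give 0.32; DNA was not analysed here, so the cause stays open.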
